A study of Mus musculus with 34 samples.

How the data were processed

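The series holds 34 libraries of mouse CAD cells in 15 groups: 6 small RNA libraries and 28 polyA RNA-seq libraries from 3 experiments. Groups were taken from the sample labels. The labels of 1 group conflict: the WT libraries at 4 days without serum are WT by title, design text and protocol, while their genotype field says mir-138 DKO, and they were analysed as WT. The design text gives mimic transfections in triplicate, the protocol in duplicate, and 2 libraries per group were analysed. For the cells labelled DKO in serum that name no transfection, none was assumed. Their titles read DKO_2, those of all transfected cells DKO, and those of the second experiment WT_2, and what the 2 marks is not stated. Per the labels, the first 2 experiments used strand-specific dUTP libraries with paired-end reads of 75 bp, the third stranded libraries with single-end reads of 50 bp.

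The deposited RNA-seq files hold raw counts per gene, made by the authors with STAR on mm9, and reads that mapped to several places were not counted. The deposited small RNA files hold raw counts per mature miRNA, for which the authors' notes name cutadapt and BWA, with unassigned reads in an entry of their own that was left out of the totals. The versions of these tools and the gene annotation are not given in the sources used here. Column 4 of the STAR counts, the strand of dUTP libraries, was used. It was first checked that column 3 held 3.18 to 3.81% of the reads assigned to genes in columns 3 and 4 together. Of 37310 gene identifiers, 32620 (87.4%) matched a symbol. Across RNA-seq libraries 4.5 to 9.7% of reads were unmapped.

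Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 and version 1.17.8 of the data.table package. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries scaled by TMM, and groups compared by the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over all genes of a comparison, at a false discovery rate of 0.05. There were 17 comparisons, 3 of them interactions. Fold changes are on the log2 scale, with standard errors (SE). Lists of genes (20) and of miRNAs (9) were fixed before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. Each list with at least 3 measured members was tested with limma's camera, with a preset correlation of 0.01 and again with an estimated one. The p-values were adjusted over all gene lists and comparisons, and apart over the miRNA lists. Under an alternative they were adjusted over all lists tested in that setting, so the number of tests can differ from the main fit. For each list the calls were also adjusted over the list alone, and counts that differed are given in those words; elsewhere they were the same. Where a group had 0 counts of a gene, a bound was computed with 3 counts over the group, and with 1 to 3 counts a ratio with its exact 95% counting interval.

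Genes were named by this rule: the targeted miRNAs and their hairpin genes; the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 CPM (50 CPM for miRNAs), groups that did not overlap and a symbol other than a predicted or clone name; up to 4 members of each list described, lowest adjusted p first; and Rhoc, Lypla1, Sirt1, Ezh2, Vim, Kdm1a, Cdk6, Mib1, Th, Mki67 and Tubb3 where their list is treated. Nfix and Ccnd3 were singled out among genes with opposite changes in DKO-labelled and mimic-treated cells after their values were seen. Some genes and 1 gene list that the rule covers are not reported here.

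The procedure was tested on simulated data made from the libraries. Changes of 2-fold were recovered for 49.3% of changed miRNAs at 3 against 3 libraries, and for 80.6, 79.1 and 92.5% of changed genes in the first, the second and the third experiment. The share of false calls was 1% for miRNAs, and 6.7, 9.1 and 4.2% for genes, so above the nominal rate in the first and second experiments. Among simulated unchanged genes, 0% of random sets had a camera p-value under 0.05 before adjustment. Genes were simulated independently of each other, so this does not measure false passes among correlated genes.

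Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, replicate number as a block, unstranded counts (column 2), the compared libraries alone, each library left out in turn, and for miRNAs scaling by library totals alone and without the most abundant miRNA. If leaving out a library left a group with 1, that sample is assumed to vary like the other groups. Tests of seed matches in 3' UTRs were planned and not run, since no genome sequence was at hand. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.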

Results

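RNA was measured in mouse CAD cells, a catecholaminergic neuronal line that stops dividing and extends processes when serum is removed. The 34 libraries fall into 15 groups. Small RNA-seq covered wild-type (WT) cells in 10% serum and 4 days after serum withdrawal, with 3 libraries in each group. The other 28 libraries are polyA RNA-seq from 3 experiments. The first experiment held WT cells and cells labelled mir-138 DKO (double knockout), in serum and 1 day after withdrawal, with 2 libraries in each of the 4 groups. The second held WT cells in serum and 4 days after withdrawal, with 3 libraries in each group. The third held only cells labelled DKO, with 2 libraries in each of 7 groups: no transfection named, in serum, and pUC19 DNA, miR-138 mimic or miR-137 mimic, each in serum and 2 days after withdrawal. Mimics were given at 3 nM, and serum was removed 48 h after transfection. Reads assigned to genes ranged from 22359075 to 41505181 per library in the first experiment, 19900317 to 28631969 in the second and 12740836 to 25582125 in the third. Reads assigned to miRNAs ranged from 1423978 to 2763553 in the small RNA libraries. Levels are CPM, read counts per 1e6 reads, scaled within each experiment, as mean ± SD of the group's libraries. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries.

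The label DKO was first set against the targeted loci. Mir138-1, a hairpin gene of miR-138, had reads in all 28 RNA-seq libraries. In the first experiment it stood at 0.62 ± 0.09 CPM of assigned reads in WT cells in serum and 1.03 ± 0.51 CPM at 1 day (n = 2 each). The cells labelled DKO had 6.7 ± 1.22 CPM in serum and 10.23 ± 1.11 CPM at 1 day (n = 2 each). Mir138-1 was therefore higher in the libraries labelled DKO, by a log2 fold change of 3.45 in serum (adjusted p = 1.52e-06) and 3.27 at 1 day (adjusted p = 1.16e-06). In the second experiment Mir138-1 had 0.67 ± 0.17 CPM in WT cells in serum and 1.59 ± 0.38 CPM at 4 days (n = 3 each). In the third experiment its group means ran from 1.06 to 2.93 CPM (n = 2 each). Mir138-2, the other hairpin gene, had 0 counts in all 28 libraries. Mir137 had reads in the second experiment alone, with 0.28 ± 0.18 CPM in serum and 0.14 ± 0.12 CPM at 4 days (n = 3 each). PolyA reads over a hairpin do not measure mature miR-138, and small RNA of the cells labelled DKO was not analysed here. These reads go against a plain loss of the Mir138-1 locus. No direct measure here shows that the cells lack miR-138, which is taken from the label DKO. Levels of reported miR-138 targets, given below, bear on it only indirectly. Other values followed the labels across experiments. In serum Tubb3, the neuronal beta-tubulin, had 25.2 to 28.3 CPM of assigned reads in the cells labelled DKO of the first experiment. In the third it had 18.9 to 32.5 CPM in those given pUC19 or no named transfection, against 452 to 499 CPM in the WT libraries of the first and second.

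The small RNA comparison asks which miRNAs change as WT cells lose serum for 4 days. mmu-miR-138-5p rose from 6750 ± 1600 to 11100 ± 310 CPM, and mmu-miR-137-3p from 5090 ± 850 to 8570 ± 290 CPM (n = 3 each). The abundant mmu-miR-182-5p rose from 22500 ± 1200 to 50400 ± 2200 CPM, and mmu-miR-210-3p, a miRNA induced by hypoxia, rose from 294 ± 18 to 5210 ± 320 CPM. Members of the miR-17-92 family of clusters, known for promoting proliferation, fell together. mmu-miR-92a-1-5p dropped from 282 ± 47 to 30.5 ± 6.1 CPM and mmu-miR-18a-5p from 4430 ± 600 to 2100 ± 110 CPM. The log2 fold change was 0.72 ± 0.17 (SE) for mmu-miR-138-5p (adjusted p = 0.0206) and 0.75 ± 0.13 for mmu-miR-137-3p (adjusted p = 0.0056). The other arm, mmu-miR-137-5p, stood at 0.62 (adjusted p = 0.0454), and its call was lost with no low-count filter, with the replicate block, with library totals alone (0.35, adjusted p = 0.176) and without any single library other than serum replicate 2, over a range of 0.00715 to 0.176. Scaling by library totals alone put mmu-miR-138-5p at 0.44 and mmu-miR-137-3p at 0.47 (adjusted p = 0.107 and 0.0413, the latter over a range of 6.75e-06 to 0.0419). The call for mmu-miR-138-5p was lost under that scaling and when a single 4-day library was left out (adjusted p = 0.0825, 0.0808 and 0.0533 without 4-day replicates 1, 2 and 3), over a range of 0.000634 to 0.107 among its alternatives. The log2 fold change of mmu-miR-138-5p was 0.694, 0.739 and 0.797 without these 4-day libraries in turn, and 0.511 without serum replicate 2. The opposite-strand mmu-miR-138-1-3p had a log2 fold change of 0.39 (adjusted p = 0.117) and mmu-miR-138-2-3p one of 1.05 (adjusted p = 0.0921). Without serum replicate 2 these opposite-strand arms stood at 0.20 (adjusted p = 0.111) and 0.705 (adjusted p = 0.0193), the latter past the threshold. With library totals alone mmu-miR-138-1-3p stood at 0.11. Their adjusted p ranged from 0.0904 to 0.656 and from 0.0193 to 0.22 among the alternatives.

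Of 715 miRNAs tested, 256 passed a false discovery rate of 0.05 at 4 days, 140 higher and 116 lower. Counted among the lower ones is a Drosophila name, dme-miR-14-5p (-0.846, adjusted p = 0.0467), whose source was not examined. The largest rises were of mmu-miR-2137 (log2 fold change 5.87), mmu-miR-210-3p (4.15, adjusted p = 2.89e-06), mmu-miR-5121 (4.07), mmu-miR-210-5p (3.88), mmu-miR-3964 (2.46), mmu-miR-598-3p (2.32), mmu-miR-1843a-5p (2.05) and mmu-miR-3535 (1.98). The largest falls were of mmu-miR-92a-1-5p (-3.22, adjusted p = 0.000119), mmu-miR-19b-1-5p (-2.58), mmu-miR-6539 (-2.54), mmu-miR-15b-3p (-2.44), mmu-miR-16-1-3p (-2.12), mmu-miR-16-2-3p (-2.09), mmu-miR-27a-5p (-1.83) and mmu-miR-218-2-3p (-1.69). Opposite-strand arms of several of these moved less. mmu-miR-15b-5p stood at -0.539 (adjusted p = 0.0156) and mmu-miR-19b-3p at -0.38 (adjusted p = 0.0313). mmu-miR-16-5p (0.077, adjusted p = 0.431), mmu-miR-27a-3p (-0.435, adjusted p = 0.292) and mmu-miR-218-5p (-0.039, adjusted p = 0.653) did not pass. In the miR-17-92 list 15 of 22 measured members fell, 0 rose and 7 did not pass, and 16 fell when adjusted over the list alone. The list's median log2 fold change was -0.66 (adjusted p = 2.46e-07, and adjusted p = 0.0352 with an estimated correlation), with mmu-miR-18a-3p at -1.04 and mmu-miR-19a-5p at -1.28. Of 11 miRNAs often linked to proliferation 1 fell, 0 rose and 10 did not pass (median -0.06, adjusted p = 0.874). None of 6 arms of the miR-34 and miR-449 families passed (median -0.10, adjusted p = 0.874), and none of 3 of the miR-200 family (median -0.93, adjusted p = 0.877). Of 43 miRNAs known from neurons, 14 rose, among them mmu-miR-344-3p (1.14) and mmu-miR-488-3p (1.02), and 6 fell, among them mmu-miR-212-3p (-1.20), while 23 did not pass. As a list they did not differ from other miRNAs (median 0.39, adjusted p = 0.432). The let-7 family had 4 members higher, 1 lower and 13 not past the threshold (2 and 1 adjusted over the list alone, adjusted p = 0.365), with mmu-let-7i-5p at 0.97. In the miR-183-96-182 cluster 3 of 6 arms rose and 1 fell (adjusted p = 0.249), with mmu-miR-182-5p at 1.16 and mmu-miR-96-5p at 1.03. The cluster passed only with no low-count filter (0.0171, adjusted there together with the gene lists), over a range of 0.0171 to 0.324. Of 48 arms from the Dlk1-Dio3 cluster, 3 fell and 0 rose, and none passed when adjusted over the list alone (median -0.79, adjusted p = 0.0876). That list passed without serum replicate 1 or 3 (adjusted p = 0.0237 and 0.000478), without 4-day replicate 1 or 2 (0.0255 and 0.0429), with no low-count filter (0.0189) and with the replicate block (0.0197), over a range of 0.000478 to 0.467. The values with no low-count filter and with the replicate block were adjusted together with the gene lists. Among markers of muscle, blood and other cell types 3 of 8 rose and 1 fell (adjusted p = 0.874), with mmu-miR-1a-3p at 0.88. Unassigned reads made up 46.1 to 49.2% of the libraries in serum and 34.1, 40 and 38.2% of those at 4 days. Scaling by library totals alone put the median of all miRNAs at -0.384, against -0.112, and gave 281 calls of which 88 were higher. The count of 256 moved to 399 without serum replicate 2, whose Pearson correlations with the other serum libraries were 0.9387 and 0.8736 across miRNAs. It was 168 without serum replicate 1, 168 without 4-day replicate 1 and 154 without 4-day replicate 2 or 3.

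**Figure D1:**
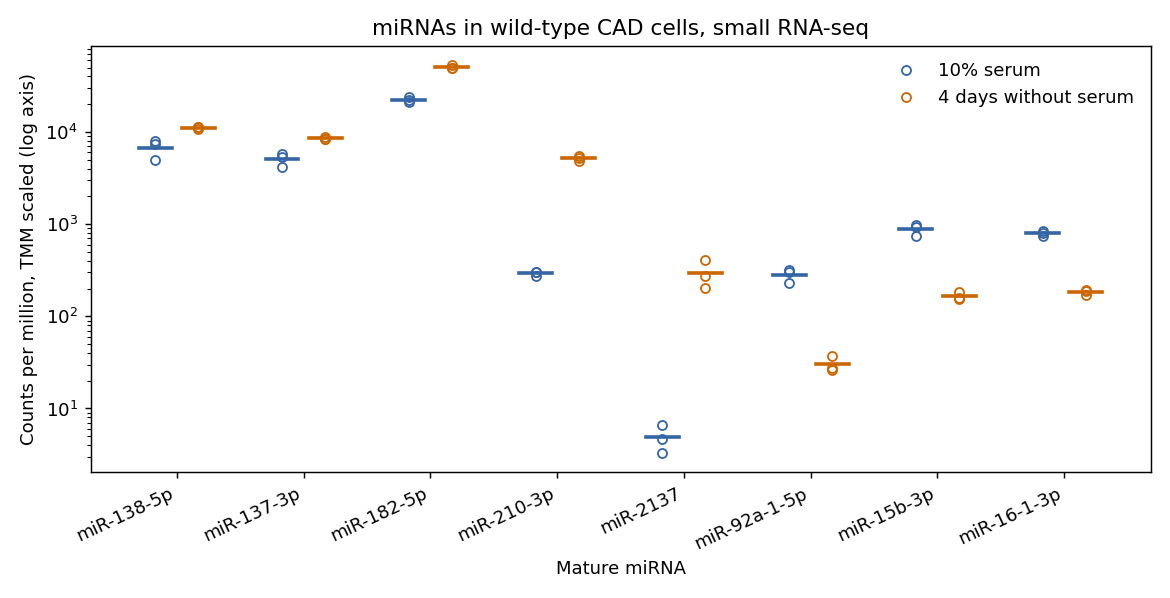
Scaled CPM (log axis) of 8 mature miRNAs in WT CAD cells in 10% serum and 4 days without serum. Each point is a library, 3 per group, and each line is the group mean; mmu-miR-210-3p goes from a mean of 294 to 5210 CPM and mmu-miR-92a-1-5p from 282 to 30.5 CPM.

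The comparison of genotypes in serum asks how gene expression differs between the cells labelled DKO and WT cells. Neuronal genes were much lower in the cells labelled DKO. Nefh, the heavy neurofilament subunit, had 4.68 ± 0.072 CPM against 432 ± 2.6 CPM in WT, and Tubb3 had 27.3 ± 2.2 against 465 ± 12 CPM (n = 2 each). Dbh, which makes noradrenaline from dopamine, stood at 5.9 ± 0.49 against 69.3 ± 5.1 CPM. Th, the first enzyme of catecholamine synthesis, had 0 counts in the cells labelled DKO against 125 in WT, which makes it at least 49.1-fold lower. Higher in the cells labelled DKO were Sox9, a transcription factor of neural and glial precursors, at 191 ± 14 against 37.6 ± 0.25 CPM, and Nfix, a nuclear factor I gene, at 251 ± 34 against 40.8 ± 6.1 CPM. Of 13630 genes tested, 5546 passed, 2618 higher and 2928 lower, with 521 and 1132 of them changed at least 2-fold.

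Of 40 neuronal structure and synapse genes measured in serum, 35 were lower in the cells labelled DKO, 2 higher and 3 not past the threshold (36 lower when adjusted over the list alone). Their median log2 fold change was -2.52 (adjusted p = 9.81e-103, and adjusted p = 0.0109 with an estimated correlation). Nefh stood at -6.53 ± 0.09 (SE, adjusted p = 1.77e-15), Ina, an intermediate filament, at -4.18, and Cplx1, a synaptic release protein, at -6.64. Among the largest falls, Gria3, an AMPA receptor subunit, was at least 242-fold lower, Vwa5b1 stood at -9.26 and St8sia3 at -8.77. Count ratios were 1030 (95% interval 184 to 40600) for Sncb, 730 (131 to 28900) for Celf6, 725 (130 to 28700) for Nckap1l and 493 (136 to 4080) for Plppr5, all lower. Intervals and floors, which take 3 counts over the group, cover counting error only. The largest rises were of Capn6 (6.87), Mgst1 (5.76), Scara5 (5.18), Myof (4.76), Chst15 (4.35), Sec16b (4.16) and Acsf2 (4.15), and Cd109 was higher by a count ratio of 239 (81.4 to 1160). ATF4-linked stress genes had 12 of 20 lower and 5 higher (median -0.41, adjusted p = 0.0269, and adjusted p = 0.482 with an estimated correlation). Catecholamine genes had 10 of 17 lower and 3 higher (median -0.33, adjusted p = 0.0571), with Cyb561 at -0.87 and Gch1 at -0.60. That list passed without WT serum replicate 1 (adjusted p = 0.0406), without DKO serum replicate 2 (0.0359), with no low-count filter (0.0196) and with the compared libraries alone (0.0382), over a range of 0.0196 to 0.0974. Lin28a and Lin28b, which block let-7 processing, were lower by -6.01 and -1.47. In the microRNA pathway list to which both belong, 10 of 21 were lower, 2 higher and 9 not past the threshold (12 and 2 adjusted over the list alone, adjusted p = 0.0364, and adjusted p = 0.443 with an estimated correlation), and the list's call was lost with no low-count filter (adjusted p = 0.0546) and without DKO serum replicate 2 (adjusted p = 0.0999), over a range of 0.00688 to 0.0999 among its alternatives.

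Reported miR-138 targets, a list drawn from earlier work on this miRNA, tended to be higher in the cells labelled DKO. In serum 14 of 25 were higher, 5 lower and 6 not past the threshold, counts that stayed the same when adjusted over the list alone. Their median was 0.32 (adjusted p = 4.57e-05, and adjusted p = 0.0642 with an estimated correlation). Beside Nfix (2.62 ± 0.11, adjusted p = 1.48e-10) and Sox9 (2.35 ± 0.08), Ccnd3, a G1 cyclin, stood at 1.72, Rhoc at 1.26, Vim, the filament protein vimentin, at 0.94 and Ezh2, a histone methyltransferase, at 0.57. Lypla1 (0.18, adjusted p = 0.118) and Sirt1 (-0.18, adjusted p = 0.224) did not pass. Reported miR-137 targets had 14 of 25 lower and 6 higher (median -0.27, adjusted p = 0.0176, and adjusted p = 0.371 with an estimated correlation), with Mib1 at -0.65. Cell cycle genes had 22 of 40 higher, 1 lower and 17 not past the threshold (23 and 2 adjusted over the list alone, median 0.28, adjusted p = 0.00166, and adjusted p = 0.446 with an estimated correlation). Mcm3 of the replication helicase stood at 0.66, while the proliferation marker Mki67 stood at 0.08 (adjusted p = 0.527). Cholesterol genes had 16 of 24 higher and 1 lower (18 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.00359, and adjusted p = 0.515 with an estimated correlation). Among markers of other cell types, fibroblast genes had 2 of 5 higher and 1 lower (adjusted p = 0.401), with Col1a2 at 4.20 and Dcn at 4.41, each under 5 CPM in every group of this experiment except Dcn at 1 day. Glial markers had 1 of 7 lower, Slc1a2, at least 144-fold, and 0 higher (adjusted p = 0.665).

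At 1 day without serum the gap in neuronal genes between genotypes was again present. Chgb, a protein of secretory granules, had 18.5 ± 3.9 CPM in the cells labelled DKO against 2890 ± 97 CPM in WT, and Tubb3 had 57.2 ± 5.4 against 847 ± 19 CPM (n = 2 each). Of 40 neuronal genes 37 were lower, 0 higher and 3 not past the threshold, with 39 lower when adjusted over the list alone (median -3.53, adjusted p = 1.26e-110, and adjusted p = 0.00323 with an estimated correlation). Chgb stood at -7.28 ± 0.15 (SE, adjusted p = 6.26e-14), L1cam, an axonal adhesion protein, at -5.83 and Nefh at -5.67. The potassium channel genes Kcnc1 and Kcnh4 were at least 449-fold and 281-fold lower, Actl6b of the neuronal chromatin remodeller at least 269-fold and Scrt2 at least 234-fold. Adgrb1 was lower by a count ratio of 731 (202 to 6050) and Nckap1l by 970 (174 to 38300), and Lin28a stood at -8.73. Capn6 (7.17), Chst15 (6.07), Myof (5.85), Ifitm3 (5.76), Mgst1 (5.49), Cd109 (5.26), Sec16b (4.70) and Arhgef37 (4.36) showed the largest rises.

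Dividing-cell genes were higher in the cells labelled DKO at 1 day. Mki67 stood at 549 ± 14 against 335 ± 7.6 CPM (log2 fold change 0.71, adjusted p = 1.43e-05), Top2a and Aurkb each at 0.95. Of 40 cell cycle genes 37 were higher, 0 lower and 3 not past the threshold (38 higher when adjusted over the list alone, median 0.62, adjusted p = 4.14e-12, and adjusted p = 0.116 with an estimated correlation). Stress genes driven by the transcription factor ATF4 had 17 of 20 higher and 1 lower (18 and 1 adjusted over the list alone, median 0.74, adjusted p = 4.08e-07, and adjusted p = 0.166 with an estimated correlation). Slc7a11, the cystine importer, stood at 2.40 and Cebpb at 1.37. The miR-138 target list had 13 of 25 higher, 4 lower and 8 not past the threshold (14 and 4 adjusted over the list alone, median 0.22, adjusted p = 5.4e-05, and adjusted p = 0.0649 with an estimated correlation). Egln3, a prolyl hydroxylase of the hypoxia pathway, stood at 262 ± 2.6 against 54.9 ± 1.3 CPM (2.26, adjusted p = 5.66e-12), Nfix at 2.59, Ccnd3 at 1.74 and Sox9 at 1.61. Catecholamine genes had 11 of 17 lower and 1 higher (median -0.30, adjusted p = 0.025, and adjusted p = 0.326 with an estimated correlation). Th had 31 counts in the cells labelled DKO at 1 day and was still lower. Its call was lost with the replicate block (-1.57, adjusted p = 0.0635) and with unstranded counts (-1.56, adjusted p = 0.0501). The immediate-early gene Egr1 stood at 115 ± 5 against 230 ± 0.72 CPM, and Jun was lower (-1.04). Of all genes tested at 1 day, 6123 passed, 2983 higher and 3140 lower. WT and DKO-labelled libraries stand together in 1 experiment alone, so genotype and any other difference between the lines could not be separated.

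Serum withdrawal in WT cells was measured at 1 day and, in another experiment, at 4 days. At 1 day the cell cycle slowed in expression: Mki67 fell from 693 ± 36 to 335 ± 7.6 CPM, and Id3, an inhibitor of differentiation factors, fell from 30.7 ± 1 to 0.221 ± 0.31 CPM (n = 2 each). Sterol synthesis rose, with Cyp51 going from 159 ± 4.1 to 595 ± 11 CPM. Neuronal genes rose, with Chgb going from 903 ± 29 to 2890 ± 97 CPM and Tubb3 from 465 ± 12 to 847 ± 19 CPM. Of 40 cell cycle genes 39 fell and 1 did not pass, adjusted over all genes or over the list alone (median -0.93, adjusted p = 5.3e-50, and adjusted p = 0.0233 with an estimated correlation). Plk1 stood at -1.44 ± 0.07 (SE, adjusted p = 4.08e-09), Ccnb1 at -1.30 and Mki67 at -1.05. Of 24 cholesterol genes 23 rose and 1 did not pass, by both adjustments (median 1.67, adjusted p = 2.56e-78, and adjusted p = 0.0209 with an estimated correlation), with Fdft1 at 2.15 and Cyp51 at 1.91. Of 40 neuronal genes 28 rose, 2 fell and 10 did not pass, by both adjustments (median 0.45, adjusted p = 1.67e-06, and adjusted p = 0.044 with an estimated correlation). Chgb stood at 1.68, Mapt, the microtubule protein tau, at 1.20 and Tubb3 at 0.86, while the adhesion gene Ncam1 fell (-1.46).

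FoxO and insulin-withdrawal genes had 14 of 18 higher and 0 lower at 1 day in WT cells (15 adjusted over the list alone, median 1.01, adjusted p = 1.69e-10, and adjusted p = 0.135 with an estimated correlation), with Pik3ip1 at 2.09 and Foxo3 at 1.17. Lysosome and autophagy genes had 18 of 26 higher and 0 lower (median 0.43, adjusted p = 7.49e-08, and adjusted p = 0.0522 with an estimated correlation), with the protease gene Ctsl at 1.31. Serum-response genes had 13 of 27 higher and 3 lower (median 0.40, adjusted p = 0.00643, and adjusted p = 0.155 with an estimated correlation), with Egr1 at 1.11 and Dusp6, an ERK phosphatase, at 0.90. ATF4-linked genes had 6 of 20 higher and 7 lower (median 0.01, adjusted p = 0.476). The largest rises were of Epha10 (3.90), Papln (3.89), Trp53inp1 (3.37), Eln (3.33), Rab27a (3.00), Col9a2 (2.94), Mettl27 (2.92) and Aldoc (2.79). The largest falls were of Id3 (-7.22 ± 0.42, adjusted p = 2.56e-08), Id2 (-4.20), Id1 (-3.10), Cyp26b1 (-3.01), Atoh8 (-2.87), Hr (-2.84), Thbs4 (-2.71) and Fst (-2.68). Dbh fell from 69.3 ± 5.1 to 11.8 ± 1.3 CPM (-2.56). Of the genes tested 5546 passed, 2781 higher and 2765 lower.

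At 4 days WT cells carried the marks of cells that had left the cycle. Mki67 fell from 487 ± 36 to 7.09 ± 5.7 CPM and Aurka, a mitotic kinase, from 126 ± 3 to 2.66 ± 0.27 CPM (n = 3 each). Ache, which breaks down acetylcholine, rose from 4.29 ± 0.43 to 1170 ± 260 CPM, Stmn4, a neuronal tubulin regulator, from 0.635 ± 0.48 to 80.4 ± 7 CPM, and Chgb from 1150 ± 27 to 7430 ± 1100 CPM. All 40 cell cycle genes fell (median -5.57, adjusted p = 2.12e-58, and adjusted p = 0.075 with an estimated correlation), with Plk1 at -6.12, Mki67 at -6.11 and Aurka at -5.56 (SE 0.12, adjusted p = 2.28e-12). Of 23 cholesterol genes 22 rose and 1 did not pass (median 1.76, adjusted p = 3.04e-19, and adjusted p = 0.0209 with an estimated correlation), with Lss at 2.71 and Cyp51 at 2.15. FoxO genes had 15 of 18 higher and 0 lower (median 1.91, adjusted p = 8.62e-11, and adjusted p = 0.044 with an estimated correlation), with Pik3ip1 at 4.70 and Foxo3 at 2.90. Of 40 neuronal genes 31 rose, 5 fell and 4 did not pass (median 0.94, adjusted p = 1e-07, and adjusted p = 0.457 with an estimated correlation), with Chgb at 2.69, Mapt at 2.57, L1cam at 2.18 and Tubb3 at 0.40. Counts of the cell cycle, cholesterol and neuronal lists were the same when adjusted over each list alone.

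Lysosome genes had 23 of 26 higher and 0 lower at 4 days (median 1.10, adjusted p = 1.39e-08, and adjusted p = 0.238 with an estimated correlation), with Ctsd at 1.87. Ribosomal protein genes had 44 of 45 lower (45 adjusted over the list alone, median -0.80, adjusted p = 5.1e-07, and adjusted p = 0.656 with an estimated correlation), with Rps2 at -1.76. Interferon-response genes had 12 of 19 higher and 1 lower (median 1.89, adjusted p = 0.0269, and adjusted p = 0.263 with an estimated correlation), with Stat2 at 2.05. Lypla1 (-1.14), Sirt1 (-1.14) and Ezh2 (-3.08) of the miR-138 target list fell, and Nfix rose (1.37). As a list the miR-138 targets did not pass (camera adjusted p from 0.342 to 0.515 among the alternatives). Dbh fell (-3.26). Ago4, an Argonaute gene, rose (2.90) and Lin28a fell (-1.55). Among the largest rises, Fmod was at least 568-fold higher, and count ratios were 1130 (202 to 44500) for Dusp26, 322 (110 to 1570) for Scara5 and 268 (91.5 to 1300) for Btnl7-ps. Ache stood at 8.09, Rab11fip5 at 7.30, Stmn4 at 7.02 and Ptgds at 6.80. Lrr1 fell by a count ratio of 624 (172 to 5160), Pif1 stood at -7.80, Ube2c at -7.75, Rrm2 at -7.71, Kif14 at -7.51, Gtse1 at -7.45, Fam83d at -7.39 and Pclaf at -6.97. Fibroblast markers moved the same way as the differentiation genes: all 8 measured were higher at 4 days (median 4.08 with genes at 0 counts fitted or at their bound, adjusted p = 0.126, and adjusted p = 0.39 with an estimated correlation). Col6a1 was at least 87.8-fold higher, Col1a2 stood at 4.87 and Col1a1 at 2.83, each under 5 CPM. Of 13283 genes tested 9417 passed, 4805 higher and 4612 lower. The 4-day libraries are WT by title and protocol but carry mir-138 DKO in their genotype field. In them the 529 genes at least 4-fold lower in the cells labelled DKO at both times had a median of 15.6 CPM, against 5.04 CPM in WT serum libraries of the same experiment and 0.205 CPM in the cells labelled DKO in serum.

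In the cells labelled DKO, 1 day without serum also went with a sterol rise and an Id fall. Cyp51 rose from 160 ± 2.3 to 556 ± 16 CPM, and Id3 fell from 46.3 ± 12 to 0.447 ± 0.18 CPM (n = 2 each). ATF4-linked stress genes rose: Slc7a11 went from 8.38 ± 0.73 to 92.1 ± 8.1 CPM, Trib3 from 11.4 ± 0.67 to 81.5 ± 7.3 CPM and Ddit3, which encodes CHOP, from 6.23 ± 0.057 to 39.8 ± 2.6 CPM. All 24 cholesterol genes rose (median 1.42, adjusted p = 9.23e-67, and adjusted p = 0.0209 with an estimated correlation), with Lss at 2.27 and Cyp51 at 1.80. Of 20 ATF4-linked genes 17 rose and 1 fell (18 and 1 adjusted over the list alone, median 0.80, adjusted p = 7.89e-24, and adjusted p = 0.044 with an estimated correlation), with Slc7a11 at 3.46 ± 0.12 (SE, adjusted p = 1.33e-10), Trib3 at 2.83, Ddit3 at 2.67 and Chac1 at 1.85. Mitochondrial and replication-dependent histone RNAs, which can track RNA quality and polyA selection, had 5 of 11 higher and 0 lower (median 0.46, adjusted p = 0.162). They passed as a list without DKO serum replicate 2 (adjusted p = 0.000105) and without DKO 1-day replicate 1 (adjusted p = 0.0415), over a range of 0.000105 to 0.289. Of 40 cell cycle genes 36 fell and 4 did not pass (37 fell adjusted over the list alone, median -0.57, adjusted p = 8.01e-21, and adjusted p = 0.0651 with an estimated correlation), with Mcm2 at -1.13 and Mki67 at -0.41. FoxO genes had 15 of 18 higher and 0 lower (17 adjusted over the list alone, median 0.90, adjusted p = 1.3e-12, and adjusted p = 0.0913 with an estimated correlation). Neuronal genes had 13 of 40 higher, 9 lower and 18 not past the threshold (adjusted p = 0.586), with Tubb3 at 1.06, Syt1 at 1.16 and Ncam1 at -1.58. Targets of p53 had 10 of 18 higher and 3 lower (11 and 4 adjusted over the list alone, median 0.55, adjusted p = 0.00024, and adjusted p = 0.166 with an estimated correlation). Among the largest rises were those of Fam57b (5.81), Kbtbd11 (5.03), Trim66 (4.76), Pnpla3 (4.24), Aldoc (3.82), Pdk1 (3.80) and Nupr1 (3.64). Falls were largest for Id3 (-6.69), Id2 (-3.77), Nsg2 (-3.48), Id1 (from 48.5 ± 13 to 6.04 ± 1.3 CPM), Myo18b (-2.97), Gpbar1 (-2.51), Atoh8 (-2.43) and Grb10 (-2.35). Of the genes tested 5497 passed, 2715 higher and 2782 lower.

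The test of the difference between genotypes in their response to withdrawal passed for 1325 genes, 730 with the more positive change in the cells labelled DKO and 595 with the more negative. Slc7a11 differed by 3.10 ± 0.16 on the log2 scale (SE, adjusted p = 1.02e-07), Trib3 by 2.38, Chac1 by 1.78 and Shmt2, of mitochondrial serine metabolism, by 1.14. Of 20 ATF4-linked genes 18 were more positive and 0 more negative (20 adjusted over the list alone, median 0.985, adjusted p = 1.25e-50, and adjusted p = 0.0209 with an estimated correlation). The mitochondrial and histone RNAs had 1 of 11 more positive and 0 more negative (2 adjusted over the list alone, median 0.39, adjusted p = 0.0706). As a list they passed without WT serum replicate 2 (adjusted p = 0.0298), WT 1-day replicate 1 (0.0144), DKO serum replicate 2 (1.36e-05) or DKO 1-day replicate 1 (0.011). They also passed with no low-count filter (0.0406) and with the replicate block (0.0484), over a range of 1.36e-05 to 0.231. Slc16a3, a lactate exporter, differed by 3.33, Fam57b by 5.83, Kbtbd11 by 4.14 and Egln3 by 1.35. Cell cycle genes had 25 of 40 more positive and 1 more negative (32 and 2 adjusted over the list alone, median 0.47, adjusted p = 4.52e-14, and adjusted p = 0.109 with an estimated correlation), with Top2a at 0.64. Neuronal genes had 9 of 40 more negative and 3 more positive (13 and 4 adjusted over the list alone, median -0.42, adjusted p = 1.76e-05, and adjusted p = 0.0615 with an estimated correlation), with Stmn2 at -2.33, L1cam at -1.38 and Gap43 at -1.33, while Tubb3 stood at 0.20 (adjusted p = 0.276). Cholesterol genes had 8 of 24 more negative and 1 more positive (8 and 2 adjusted over the list alone, median -0.19, adjusted p = 0.00735, and adjusted p = 0.544 with an estimated correlation). That list's call was lost without WT serum replicate 2 (adjusted p = 0.0532) and without DKO serum replicate 1 (adjusted p = 0.0622), over a range of 0.000127 to 0.0622 among its alternatives. The differences of Id1, Id2 and Id3 did not pass (adjusted p = 0.878, 0.663 and 0.778). Egr1 (-1.17), Rhoc (-0.99) and Jun (-0.97) were more negative. The count of 1325 depended on single libraries. It was 695 and 615 without WT serum replicate 1 and 2, 638 and 660 without WT 1-day replicate 1 and 2, 2602 and 2292 without DKO serum replicate 1 and 2, and 699 and 691 without DKO 1-day replicate 1 and 2.

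**Figure D2:**
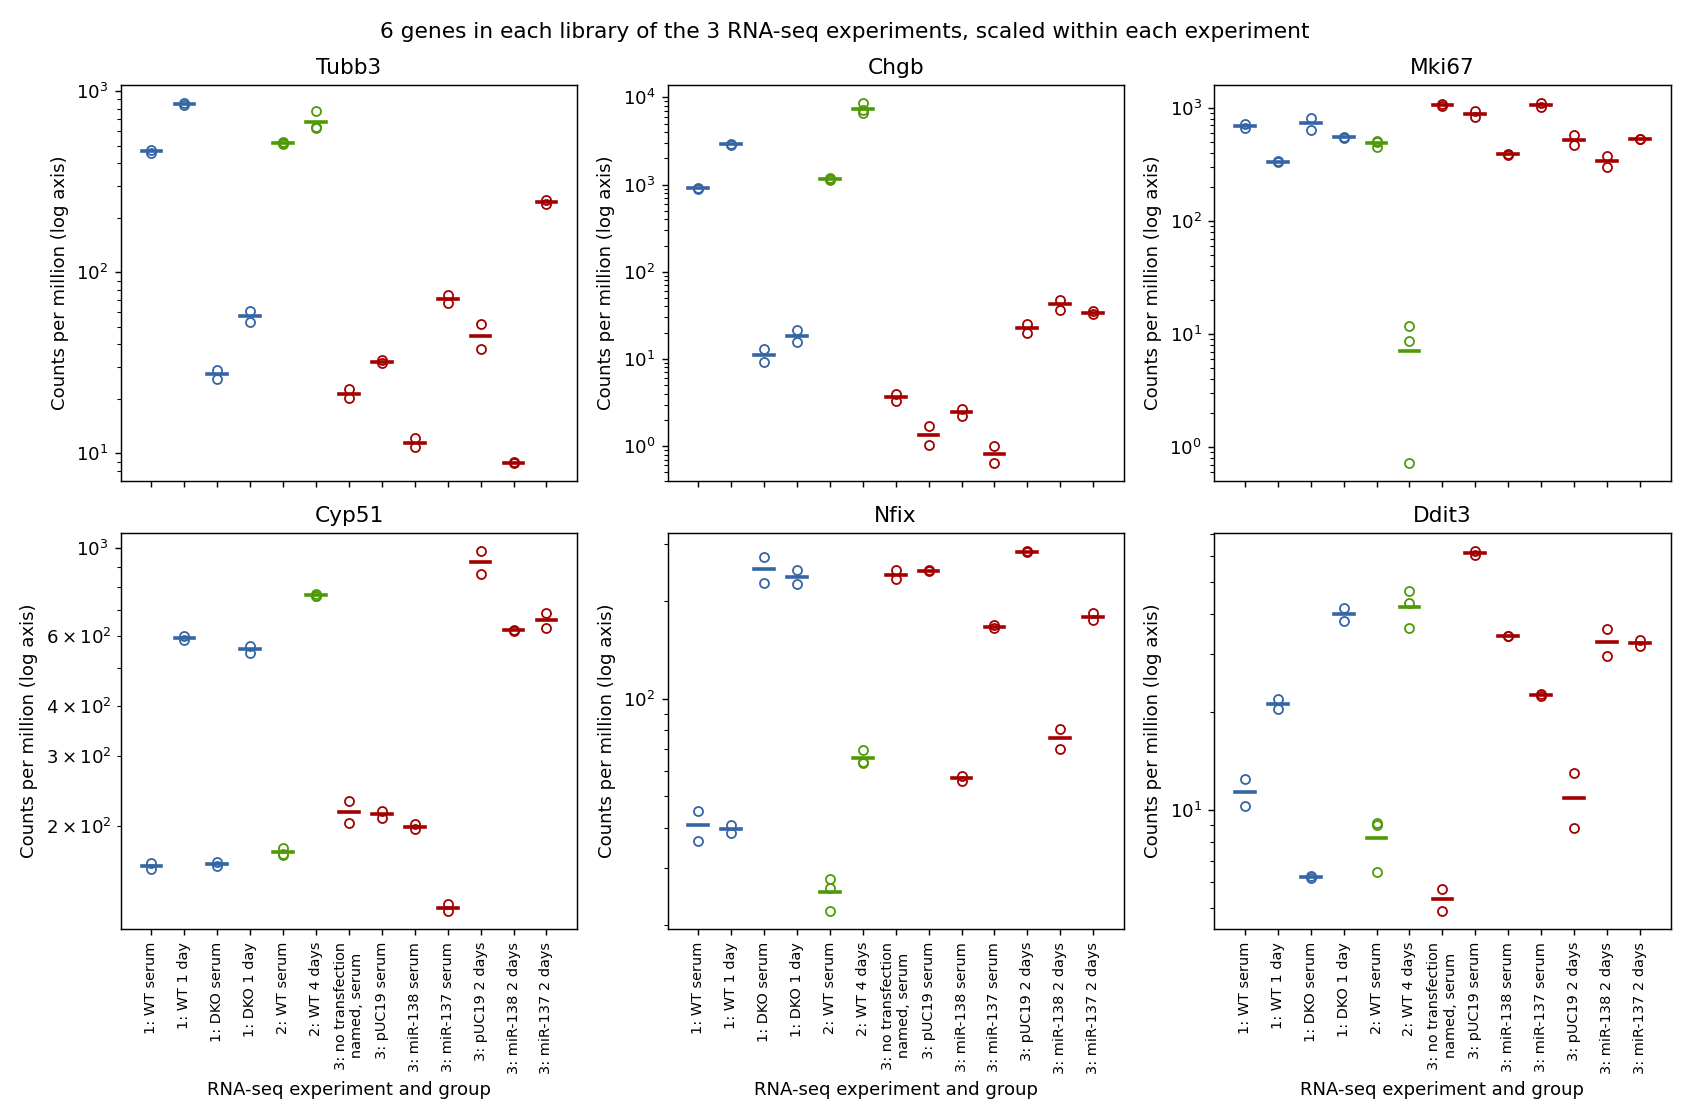
Scaled CPM (log axes, scaled within each experiment) of Tubb3, Chgb, Mki67, Cyp51, Nfix and Ddit3 in each RNA-seq library of the 13 groups, with lines at group means. Group means of Tubb3 lie between 465 and 847 CPM in WT cells and between 8.9 and 244 CPM in cells labelled DKO; among the latter, Nfix is lowest with the miR-138 mimic, at 56.9 and 75.4 CPM.

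The third experiment also allows pUC19 cells to be set against cells with no transfection named. Titles of the latter read DKO_2 and those of all transfected cells DKO, so transfection and any other difference between these cells were not separated. In serum, cells given pUC19 DNA had more stress-response RNA than cells with no transfection named: Ddit3 stood at 61.4 ± 1.1 against 5.32 ± 0.6 CPM and Slc7a11 at 179 ± 8 against 38.8 ± 3.7 CPM (n = 2 each). ATF4-linked genes had 13 of 19 higher and 1 lower, by both adjustments (median 0.66, adjusted p = 1.03e-40, and adjusted p = 0.00218 with an estimated correlation), with Ddit3 at 3.52 ± 0.13 (SE, adjusted p = 1.86e-13), Trib3 at 2.48, Slc7a11 at 2.21 and Ppp1r15a at 2.10. Serum-response genes had 16 of 26 higher and 1 lower (20 and 2 adjusted over the list alone, median 0.83, adjusted p = 2.9e-27, and adjusted p = 0.0268 with an estimated correlation), with Atf3 at 3.65 and Egr1 at 1.92. The p53 targets had 8 of 18 higher and 4 lower (8 and 6 adjusted over the list alone, median 0.09, adjusted p = 1.78e-06, and adjusted p = 0.0209 with an estimated correlation), with Gdf15 at 3.47 and Cdkn1a, a CDK inhibitor, at 1.62. Among 40 cell cycle genes 24 were lower and 1 higher (25 and 1 adjusted over the list alone, median -0.24, adjusted p = 2.05e-05, and adjusted p = 0.656 with an estimated correlation). Vgf (4.34) and Dusp8 (3.30) were among the largest rises, as were the ribosomal pseudogenes Rpl12-ps1 (3.15), Rpl10a-ps1 (2.95) and Rps12-ps10 (2.82), whose reads can be shared with their parent genes. Mitochondrial mt-Nd6 fell (-1.77), as did Snrpg (-1.71) and St6galnac5 (-1.35). H3f3a fell as well (-1.20), and its direction reversed with unstranded counts (1.03, adjusted p = 6.5e-07, over a range of 7.43e-68 to 6.5e-07 among its alternatives). Of the genes tested 3321 passed, 1357 higher and 1964 lower, a balance that turned with the compared libraries alone (2990 passed, 1618 higher). The count of 3321 was 1730 without replicate 1 of the cells with no transfection named and 1750 without pUC19 serum replicate 2.

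In pUC19 cells 2 days without serum went with a sterol rise and an Id fall, as at 1 day without transfection. Cyp51 rose from 214 ± 5.9 to 923 ± 86 CPM and Id3 fell from 99.9 ± 8.2 to 0.685 ± 0.2 CPM, while Slc7a11 fell from 179 ± 8 to 32.4 ± 3.3 CPM (n = 2 each). All 24 cholesterol genes rose (median 1.54, adjusted p = 8.02e-44, and adjusted p = 0.0402 with an estimated correlation), with Lss at 2.15 and Dhcr7 at 1.73. ATF4-linked genes had 16 of 19 lower and 1 higher, by both adjustments (median -0.97, adjusted p = 3.56e-16, and adjusted p = 0.0116 with an estimated correlation), with Slc7a11 at -2.47, Trib3 at -2.19 and Ppp1r15a at -2.05. Of 40 cell cycle genes 36 were lower and 0 higher (median -0.52, adjusted p = 6.3e-09, and adjusted p = 0.515 with an estimated correlation), and FoxO genes 14 of 18 higher and 0 lower (median 1.05, adjusted p = 4.76e-10, and adjusted p = 0.122 with an estimated correlation). Neuronal genes had 16 of 36 higher, 8 lower and 12 not past the threshold (adjusted p = 0.546), with Syt1 at 1.54, Ncam1 at -2.40 and L1cam at -2.10. The largest rises were of Papln (5.43), Cbr2 (5.22), Fam57b (5.02), Kbtbd11 (5.01), Abca1 (4.90), Tll2 (4.64), St6galnac5 (4.57) and Kcnt1 (4.53). The largest falls were of Id3 (-7.15), Galnt5 (-5.73), Id2 (-5.45), Hmox1 (-3.94), Id1 (-3.81), Vgf (-3.22), Tlx2 (-3.11) and Trim66 (-3.01). Fibroblast markers had 5 of 7 higher (adjusted p = 0.0829), with Dcn at 2.08, and glial markers 4 of 5 (adjusted p = 0.111), with Aqp4 at 2.18. Of the genes tested 7552 passed, 3588 higher and 3964 lower.

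The miR-138 mimic was set against pUC19 DNA in the cells labelled DKO. No group had a control mimic, so an effect of the miRNA was not separated from one of pUC19. Slc7a11, Gdf15, Vgf and Cdkn1a, which fell with the mimic in serum, were higher with pUC19 than with no transfection named. In serum, reported miR-138 targets fell as a group. Nfix fell from 249 ± 1.6 to 56.9 ± 1.4 CPM, Ccnd3 from 155 ± 7.2 to 48.9 ± 1.8 CPM and Rhoc from 108 ± 0.28 to 45.8 ± 1.1 CPM (n = 2 each). Of 25 listed targets 20 fell, 2 rose and 3 did not pass (21 fell adjusted over the list alone, median -0.70, adjusted p = 2.38e-15, and adjusted p = 0.0137 with an estimated correlation). Nfix stood at -2.13 ± 0.06 (SE, adjusted p = 7.26e-15), Ccnd3 at -1.66, Rhoc at -1.24, Ezh2 at -1.06, Sirt1, a deacetylase, at -0.99, Rock2, a kinase of the actin cytoskeleton, at -0.98, Lypla1, a depalmitoylating enzyme, at -0.92 and Vim at -0.79. Reported miR-137 targets had 11 of 22 lower and 5 higher (11 and 6 adjusted over the list alone, adjusted p = 0.853), and Mib1 of that list stood at 0.08 (adjusted p = 0.213). Cell cycle genes had 37 of 40 lower and 1 higher (38 and 1 adjusted over the list alone, median -0.73, adjusted p = 2.67e-20, and adjusted p = 0.285 with an estimated correlation). Mki67 fell from 884 ± 77 to 391 ± 5 CPM (-1.18), Rrm2 stood at -1.48 and Cdkn1a at -2.02. ATF4-linked genes had 17 of 19 lower and 1 higher (median -0.51, adjusted p = 2.33e-09, and adjusted p = 0.0213 with an estimated correlation), with Slc7a11 at -1.76 and Trib3 at -1.19. Serum-response genes had 17 of 26 lower and 2 higher (median -0.58, adjusted p = 2.07e-06, and adjusted p = 0.253 with an estimated correlation), with Ier3 at -1.73. Neuronal genes had 10 of 36 higher, 14 lower and 12 not past the threshold (median -0.18, adjusted p = 0.915): Syt1, the calcium sensor of synaptic vesicles, rose (1.44) and Tubb3 fell from 32.1 ± 1.1 to 11.4 ± 0.92 CPM (-1.49).

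The largest rises with the miR-138 mimic in serum were of Sstr2 (2.14), Epha4 (1.89), Bphl (1.88), Pold4 (1.83), Myo16 (1.72), Tmem231 (1.69), Chrna3 (1.65) and Hdac11 (1.63). Large falls included those of Gdf15 (-2.90), Vgf (-2.65), Mcam (-2.63), Trim66 (-2.35), Nfix (-2.13), Ethe1 (-2.04) and Hmox1 (-2.03). Of 12655 genes tested 7089 passed, 3631 higher and 3458 lower, with 433 and 473 changed at least 2-fold.

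At 2 days without serum the miR-138 mimic left the listed targets low. Nfix stood at 75.4 ± 7.7 against 284 ± 1.9 CPM and Ccnd1, a G1 cyclin, at 48.4 ± 0.29 against 170 ± 16 CPM (n = 2 each). Slc40a1, the iron exporter ferroportin, rose from 10 ± 0.37 to 405 ± 33 CPM. Of 25 listed targets 19 were lower, 1 higher and 5 not past the threshold (21 and 1 adjusted over the list alone, median -0.45, adjusted p = 6.88e-11, and adjusted p = 0.0209 with an estimated correlation). Nfix stood at -1.92, Ccnd1 at -1.81, Ccnd3 at -1.55, Egln3 at -1.31, Sirt1 at -0.86, Ezh2 at -0.80, Lypla1 at -0.76, Rhoc at -0.41 and Vim at -0.25. Of 40 cell cycle genes 36 were lower (median -0.64, adjusted p = 1.67e-12, and adjusted p = 0.443 with an estimated correlation), with Tyms at -1.75. Neuronal genes had 20 of 36 higher, 7 lower and 9 not past the threshold (median 0.33, adjusted p = 0.00491, and adjusted p = 0.116 with an estimated correlation). Stmn2, a tubulin regulator of growing axons, stood at 2.86, Cntn1 at 2.32, Ncam1 at 1.42 and Syt1 at 1.31, whereas Tubb3 was lower (-2.32 ± 0.13, adjusted p = 2.05e-11). Ddc, which makes dopamine, rose (2.70). Lysosome genes had 18 of 26 higher and 2 lower (median 0.44, adjusted p = 2.12e-06, and adjusted p = 0.286 with an estimated correlation), and interferon-response genes 12 of 21 higher and 0 lower (median 0.85, adjusted p = 0.000771, and adjusted p = 0.352 with an estimated correlation), with Ddx58, an RNA sensor, at 1.41. Serum-response genes had 17 of 26 lower and 1 higher (median -0.56, adjusted p = 9.26e-07, and adjusted p = 0.238 with an estimated correlation), with Myc at -1.44. Ribosomal protein genes had 29 of 45 lower and 0 higher (median -0.38, adjusted p = 0.000161, and adjusted p = 0.297 with an estimated correlation).

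The largest rises with the miR-138 mimic at 2 days were of Slc40a1 (5.34 ± 0.09, adjusted p = 6.25e-19), Myo7a (4.57), Cdk15 (3.37), Itpka (3.29), Hist1h1c (3.25), Elfn1 (3.15), Hist1h2bc (3.06) and mt-Tt (2.96). Large falls included those of Fam57b (-4.30), Kcnt1 (-3.71), Fmnl1 (-3.44), Sertad4 (-3.24), Upp1 (-3.05), Cbr2 (-2.79) and Tll2 (-2.64). Mitochondrial and replication-dependent histone RNAs moved with the mimic at 2 days: all 8 measured were higher (median 0.64, adjusted p = 4.72e-06, and adjusted p = 0.238 with an estimated correlation), with mt-Nd5 at 0.71. In serum 3 of the 8 were higher and 0 lower (adjusted p = 0.0856, and 0.0434 with the compared libraries alone, over a range of 0.0434 to 0.148). At 2 days 7851 genes passed, 3914 higher and 3937 lower. The mimic's effect differed between the times for 3522 genes, 1684 more positive at 2 days and 1838 more negative. Of the mitochondrial and histone RNAs 5 of 8 were more positive at 2 days and 0 more negative (7 adjusted over the list alone, median 0.51, adjusted p = 2.44e-05, and adjusted p = 0.261 with an estimated correlation). Slc40a1 differed by 4.56, Ddit3 by 2.44, Ncam1 by 1.68 and Mycn by -1.97.

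With the miR-137 mimic, again set against pUC19, its own reported targets were lower. In serum Cdc42, a small GTPase of cell polarity, fell from 586 ± 52 to 234 ± 5.2 CPM and Mib1, a ubiquitin ligase of Notch signalling, from 199 ± 9.6 to 117 ± 6.4 CPM (n = 2 each). Of 22 listed targets 17 fell, 1 rose and 4 did not pass, by both adjustments (median -0.76, adjusted p = 7.09e-17, and adjusted p = 0.0209 with an estimated correlation). Cdc42 stood at -1.33 ± 0.06 (SE, adjusted p = 1.51e-12), the histone demethylase gene Kdm5b at -1.16, Tcf4 at -0.94, Ncoa3 at -0.90, Mib1 at -0.77 and the histone demethylase gene Kdm1a at -0.45, while Ezh2 of that list stood at -0.01 (adjusted p = 0.943). Reported miR-138 targets had 9 of 25 higher and 4 lower (10 and 4 adjusted over the list alone, adjusted p = 0.777). Tubb3 rose from 32.1 ± 1.1 to 71.1 ± 5.5 CPM (1.15), the neuronal RNA-binding gene Elavl4 stood at 1.05, and Syt1, a listed miR-137 target, fell (-1.23). ATF4-linked genes had 13 of 19 lower and 2 higher (median -0.41, adjusted p = 2.36e-06, and adjusted p = 0.044 with an estimated correlation), and cholesterol genes 19 of 24 lower and 1 higher (median -0.36, adjusted p = 6.59e-05, and adjusted p = 0.489 with an estimated correlation), with Cyp51 at -0.78. Cell cycle genes had 21 of 40 higher and 3 lower (21 and 4 adjusted over the list alone, median 0.25, adjusted p = 0.00645, and adjusted p = 0.79 with an estimated correlation). The largest rises were of Celf3 (1.79), Ankrd45 (1.79), Thbs1 (1.77), Cish (1.73), Nptx1 (1.64), Arid3a (1.58), Mycn (1.55) and Prkx (1.53). Falls were largest for Ap1s3 (-2.17), Lpp (-2.10), Scarb1 (-2.10), Rims4 (-2.06), Anapc13 (-2.03), Slc7a11 (-1.99), Nutf2 (-1.88) and Ahcyl1 (-1.87). Of the genes tested 5769 passed, 2921 higher and 2848 lower.

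At 2 days without serum the miR-137 mimic went with higher neuronal genes. Tubb3 stood at 244 ± 11 against 44.7 ± 9.7 CPM, L1cam at 53.7 ± 0.81 against 9.97 ± 1.1 CPM and Gap43, a growth cone protein, at 62.5 ± 1.3 against 15.9 ± 2.2 CPM (n = 2 each). Of 36 neuronal genes 18 were higher, 9 lower and 9 not past the threshold, by both adjustments (median 0.49, adjusted p = 1.12e-05, and adjusted p = 0.035 with an estimated correlation). Tubb3 stood at 2.46 ± 0.10 (SE, adjusted p = 5.53e-13), L1cam at 2.43, Gap43 at 1.97, Syn1 at 2.88 and Uchl1 at 0.92, and Syt1 at -0.69. Listed miR-137 targets had 15 of 22 lower and 0 higher (16 adjusted over the list alone, median -0.40, adjusted p = 8.06e-09, and adjusted p = 0.044 with an estimated correlation), with Mitf at -1.33, Tcf4 at -0.92 and Mib1 at -0.63, while Kdm1a stood at -0.07 (adjusted p = 0.249). ATF4-linked genes had 16 of 19 higher and 1 lower, by both adjustments (median 0.36, adjusted p = 1.09e-05, and adjusted p = 0.0611 with an estimated correlation), with Ddit3 at 1.59 and Asns at 0.80. Lysosome genes had 16 of 26 higher and 3 lower (17 and 3 adjusted over the list alone, median 0.26, adjusted p = 5.45e-05, and adjusted p = 0.39 with an estimated correlation), and ribosomal protein genes 31 of 45 lower and 0 higher (32 adjusted over the list alone, median -0.40, adjusted p = 1.6e-07, and adjusted p = 0.155 with an estimated correlation). Mki67 stood at 0.02 (adjusted p = 0.875), and cell cycle genes did not pass as a list. Without pUC19 2-day replicate 2 the median of that list was -0.276. The mimic's effect on cell cycle genes did differ as a list between serum and 2 days.

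The largest rises with the miR-137 mimic at 2 days were of Celf3 (4.70), Trim66 (3.65), Vgf (3.54), C1qtnf6 (3.04), Ptprn (2.94), Syn1 (2.88), Dysf (2.50) and Tubb3 (2.46). The largest falls were of Dbh (-2.89), Fam57b (-2.70), Phlda2 (-2.50), Papln (-2.09), Cbr2 (-2.03), Rims4 (-1.98), Nos1 (-1.97) and Diras2 (-1.95), and Cdkn1a rose (2.33). At 2 days 5406 genes passed, 2598 higher and 2808 lower. The mimic's effect differed between the times for 2945 genes, 1507 more positive at 2 days and 1438 more negative, with Vgf at 3.59, Ddit3 at 3.04, L1cam at 2.20, Tubb3 at 1.31 and Mycn at -1.21.

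Set directly against each other, the mimics moved several genes apart. Not all lists differed: neuronal and ribosomal protein genes at 2 days, and ATF4-linked genes in serum, did not pass. In serum Syt1 was higher with miR-138 than with miR-137 (131 ± 1.5 against 20.7 ± 0.8 CPM, n = 2 each, log2 fold change 2.67), as were Kdm5b (1.94) and Cdc42 (1.44). Ccnd3 (-2.13), Rhoc (-1.71), Nfix (-1.55) and Vim (-1.09) were lower with miR-138, as were Cdkn1a (-2.97) and Tubb3 (-2.64). Listed miR-138 targets had 19 of 25 lower and 4 higher (median -0.84, adjusted p = 9.77e-11, and adjusted p = 0.0209 with an estimated correlation), and listed miR-137 targets 18 of 22 higher and 4 lower (median 0.77, adjusted p = 1.09e-07, and adjusted p = 0.0615 with an estimated correlation). Cell cycle genes had 38 of 40 lower with miR-138 and 2 higher (median -0.98, adjusted p = 1.12e-20, and adjusted p = 0.28 with an estimated correlation). At 2 days Tubb3 stood at 8.9 ± 0.064 with miR-138 against 244 ± 11 CPM with miR-137 (-4.78), Vgf at -4.72, Ptprn at -4.35 and Cdkn1a at -4.09, while Slc40a1 (6.00), Ddc (5.44) and Cntn1 (3.41) were higher with miR-138. The 8 mitochondrial and replication-dependent histone RNAs were all higher with miR-138 at 2 days as well (median 0.45, adjusted p = 0.00013, and adjusted p = 0.286 with an estimated correlation). The miR-138 list had 19 of 25 lower and 3 higher (median -0.64, adjusted p = 2.44e-10, and adjusted p = 0.0209 with an estimated correlation). In serum 8019 genes passed, 4133 higher and 3886 lower, and at 2 days 7794, 3894 higher and 3900 lower.

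**Figure D3:**
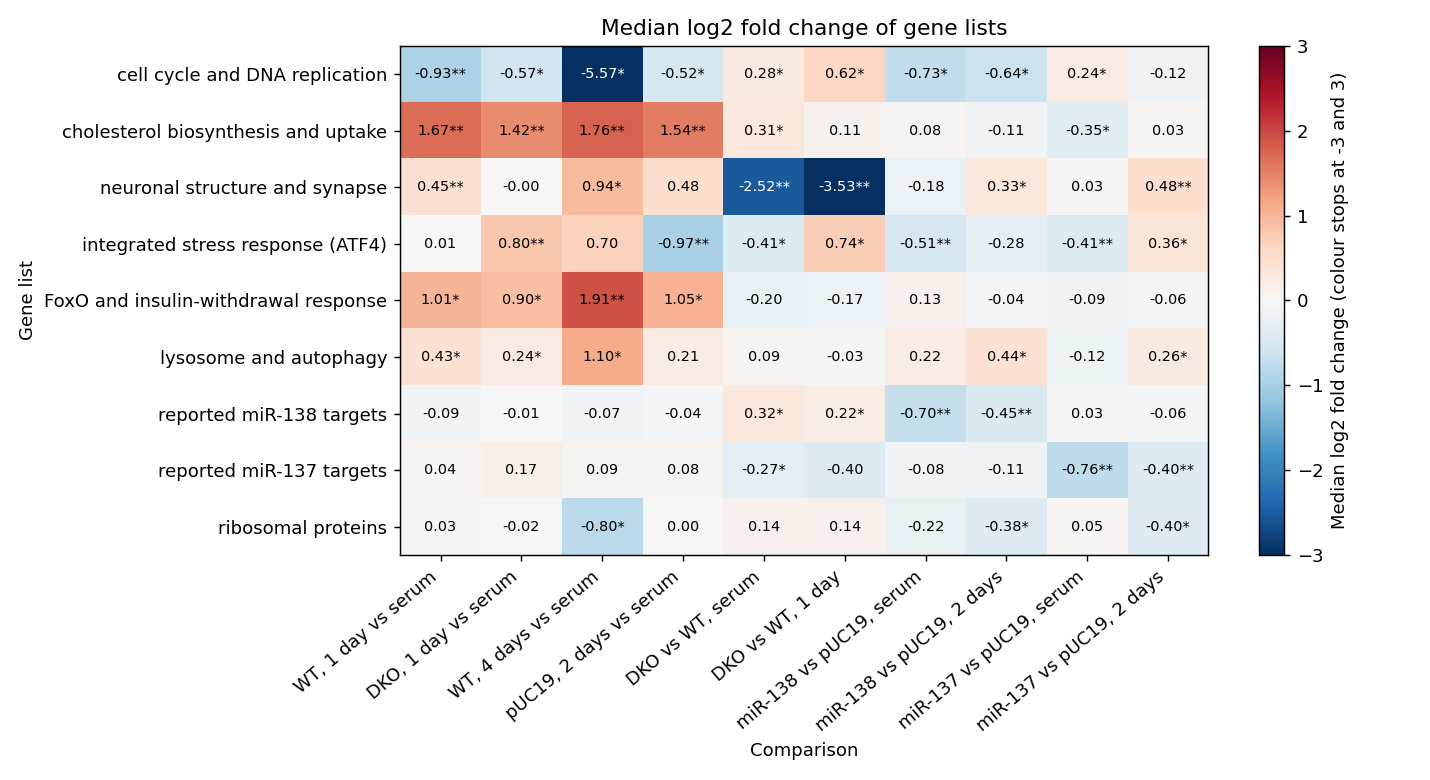
Median log2 fold change of 9 gene lists (vertical axis) in 10 comparisons (horizontal axis), coloured from -3 to 3. A single star marks an adjusted p under 0.05 with the preset correlation alone and a pair of stars one that also holds with an estimated correlation; cholesterol genes are positive in all 4 withdrawal comparisons, from 1.42 to 1.76, and each target list is lowest under its own mimic.

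Log2 fold changes were also compared across genes between experiments, where genes are not independent replicates. WT cells at 1 day and 4 days had a Pearson correlation of 0.67 and a Spearman correlation of 0.73 over 12997 genes. Of these, 2296 genes rose at both times against 986 expected from the separate counts, and 2447 fell at both against 972. The withdrawal response of the cells labelled DKO and that of pUC19 cells had correlations of 0.59 and 0.67 over 12388 genes, and the WT and DKO-labelled responses at 1 day had 0.43 and 0.59 over 13630 genes. The difference DKO against WT and the effect of the miR-138 mimic share no libraries. Their Pearson and Spearman correlations were -0.09 and -0.11 in serum, and -0.19 and -0.23 without serum, at 1 day for the genotypes and 2 days for the mimic. Higher in the cells labelled DKO and lower with the mimic at both times were 632 of 12388 genes, against 348 expected, among them Nfix and Ccnd3. The opposite pair, lower in the cells labelled DKO and higher with the mimic, held for 436 genes against 352 expected.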

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

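All tests of explanations in this part were chosen only after the result was seen, and the criteria of the reversal test and of the raised-level test were tightened, and the scaling tests replaced, after their values were seen. Responses that differed between groups by an interaction test were singled out. The response to serum withdrawal differed between the cells labelled DKO and WT cells for 1325 genes. The effect of the miR-138 mimic differed between serum and 2 days without it for 3522 genes, and that of the miR-137 mimic for 2945 genes. ATF4-linked stress genes differed as a list in each: the median difference was 0.985 between genotypes (adjusted p = 1.25e-50), 0.454 for the miR-138 mimic (adjusted p = 9.55e-09) and 0.623 for the miR-137 mimic (adjusted p = 4.6e-27). With an estimated correlation their adjusted p-values were 0.0209, 0.0268 and 0.00402. Both mimic differences subtract the same change of the pUC19 cells on withdrawal, in which this list fell. They are therefore not independent of each other or of that fall. Mitochondrial and replication-dependent histone RNAs, which can track RNA quality, differed too for the miR-138 mimic (median 0.514, adjusted p = 2.44e-05, and adjusted p = 0.261 with an estimated correlation). Between genotypes their median difference was 0.392 (adjusted p = 0.0706), past the threshold under 6 alternatives, the replicate block among them (0.0484), over a range of 1.36e-05 to 0.231. For the miR-137 mimic the median was -0.028 and the mean 0.328 (adjusted p = 0.304, and 0.0146 without miR-137 serum replicate 2, over a range of 0.0146 to 0.938). Over the ATF4 list alone 20 of 20, 11 of 19 and 16 of 19 genes had the more positive change.

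Neuronal genes were far lower in the cells labelled DKO than in WT. Scaling between libraries is argued against: the list's median less that of the other genes, which no scaling factor changes, was -2.51 in serum (bootstrap -5.63 to -1.45). Bootstrap intervals in this part resample genes as if independent, not libraries, so they leave out the spread between libraries. Loss of miR-138 may contribute, yet the test leaves this open. Of 529 genes at least 4-fold lower in the cells labelled DKO at both times, 236 passed the low-count filter in the mimic experiment. That filter used all groups, so genes near 0 with pUC19 could pass through a rise with a mimic. With the miR-138 mimic their median log2 fold change was 0 in serum (43 higher, 59 lower). At 2 days it was 0.41 (bootstrap 0.26 to 0.65, 92 higher, 39 lower), which this filter may have raised. With the miR-137 mimic at 2 days it was 0.4. Directly against the miR-137 mimic at 2 days, the median with miR-138 was -0.09 (bootstrap -0.3 to 0.15, 74 higher, 78 lower). Another difference between the cell lines could also account for it and cannot be told apart, as 1 experiment alone holds both WT and DKO-labelled libraries.

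ATF4-linked genes rose on withdrawal in the cells labelled DKO of the first experiment and fell in the pUC19 cells of the third. Scaling is argued against, since the list's median less that of the other genes was 0.79 in the first (bootstrap 0.49 to 2.25) and -0.95 in the third (-1.18 to -0.62). A raised level in transfected cells in serum is a candidate explanation that stays open, and the cells without transfection carry another title, DKO_2. Set against cells with no transfection named in serum, pUC19 cells at 2 days had a list median of -0.22 (bootstrap -0.66 to 0.29), with 6 of 19 genes higher and 9 lower, an interval too wide to decide. The experiments also differ in the day of sampling, 1 against 2, which was not tested.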

How the results depend on the processing

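Counts of changed genes or miRNAs stayed within 1.5 times their value under DESeq2, RLE scaling, no low-count filter, the replicate block, unstranded counts and the compared libraries alone, in each comparison where these were run. The share of higher ones among them crossed 50% under at least 1 alternative other than a left-out library in 14 of 17 comparisons. With replicate number as a block, 196 miRNAs passed, as did 1751 genes for the genotype by withdrawal interaction. Deviations from the group mean in replicates of the same number were correlated between groups; with 2 libraries per group both numbers give 1 value. In the first experiment all 6 values were positive (0.043 to 0.147) and 3 were over 0.1, and in the third 7 of 21 were (-0.328 to 0.298), as were 0 of 3 in each of the others. Not all values passed 0.1 in any experiment, so the numbers were not taken to pair samples, though a weak shared factor in the first is not excluded. Leaving out single libraries moved 3 counts by more. Changed miRNAs ranged from 154 (without 4-day replicate 2 or 3) to 399 (without serum replicate 2), with 168 without serum replicate 1 or 4-day replicate 1. The genotype interaction ranged from 615 (without WT serum replicate 2) to 2602 (without DKO serum replicate 1), and all 8 libraries moved it. The pUC19 difference ranged from 1730 (without replicate 1 of the cells with no transfection named) to 2764, with 1750 without pUC19 serum replicate 2. The cause was not tested. One named value reversed: H3f3a, pUC19 against no transfection named, at 1.034 with unstranded counts. Of values of named genes, DESeq2 kept 1542 of 1587 on their side of the threshold, RLE scaling 1603 of 1608 and leave-one-out 7534 of 7890. Of list tests, leave-one-out kept 1486 of 1536. Tests of seed matches were not run. Simulated 1.5-fold changes were recovered for 26.9% of miRNAs, and for 71.6, 70.1 and 80.6% of genes in the first, the second and the third experiment. Depth was not varied. Replicate small RNA libraries differed by 6.8 to 107.4 times the variance of counting (chi-square per degree of freedom), so counting depth was not their only limit.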

Other observations

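The test of hairpin reads in this part was chosen only after the result was seen; the counts over other splits were planned. CDK inhibitor and quiescence genes moved both ways on serum withdrawal in WT cells. In WT cells at 1 day Btg2, an antiproliferative gene, rose from 5.69 ± 0.23 to 25.4 ± 3.4 CPM (n = 2 each, log2 fold change 2.16), and Ccng2, a cyclin of quiescent cells, rose as well (1.40). Of 11 list members 4 rose and 3 fell at 1 day (median 0.14, adjusted p = 0.272). At 4 days Ccng2 stood at 3.52, Btg2 at 3.25 and Btg1 at 1.68, while Cdkn2c fell (-1.51). Of the 11 members 7 rose and 2 fell at 4 days (median 0.80, adjusted p = 0.111). The list passed without WT serum replicate 1 (adjusted p = 0.0437) and with no low-count filter (adjusted p = 0.0447), over a range of 0.0437 to 0.133 among its alternatives. In serum Gas1, a growth arrest gene, and Cdkn2a, the Ink4a/Arf locus, were higher in the cells labelled DKO, at 1.74 and 1.15, with 5 of 11 list members higher and 2 lower (median 0.25, adjusted p = 0.0786).

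Effects of the mimics on all genes were positively correlated, at 0.15 in serum and 0.3 at 2 days (Pearson, across genes). Both are measured against the same pUC19 libraries, and in simulations with no change these alone brought correlations of 0.55 and 0.47, above those observed. The covariance, which real changes of either mimic alone do not dilute, was 0.0474 in serum and 0.0326 at 2 days in simulations, against 0.054 and 0.131 observed. An error common to both control libraries of a time is not in these simulations.

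Mir138-1 hairpin reads were higher in the cells labelled DKO of the first experiment than in those of the third. Shorter single-end reads counted over hairpins may account for this. The log2 ratio of the third over the first experiment in serum was -2.22, within the range of 8 other hairpin genes (5th percentile -4.86, 95th 0.43). These genes are too few to decide.

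The 6 small RNA libraries and the 6 libraries of the second experiment each allow 10 splits into 3 and 3, too few for a share under 0.05. In each, 1 split, the real one, gave as many calls: 256 miRNAs and 9417 genes, with 0 as the highest of the others.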
